A study of Homo sapiens with 10 samples.

How the data were processed

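The series holds RNA-seq of the melanoma cell line A375p treated for 2 h with 10 µM DEL22379, 10 µM SCH772984 or DMSO. Per the labels, RNA was extracted with RNeasy columns and libraries of polyadenylated RNA were made with a stranded mRNA kit. There were 10 libraries, 4 with DMSO, 3 with DEL22379 and 3 with SCH772984. Sample titles run in 1 series across the groups and share no replicate numbers apart from control replicates 1 and 2, and the labels give no batch, date or pairing. Per the submitters' processing notes, reads were aligned with TopHat to hg19 and quantified with Cufflinks, whose versions are not given in the sources used here.

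The authors deposited a table of FPKM for 25275 gene entries in all 10 libraries, in which the lowest value is 0.001. They also deposited a comparison table for each compound that holds, per the file headers, the log2 FPKM of control and compound, their log2 ratio as calculated by the authors, and the authors' q-value. The file headers name no further step. The design assumed plain FPKM, but the deposited FPKM table had lost decimal points in 107207 of 252750 values (42.4%), where the digits were printed in groups parted by commas and the scale was lost. These points were put back before anything else was computed. A value printed with its point was kept. For each other value, the possible places of the point were compared with the authors' deposited FPKM of the same gene and group, allowing for an offset of each library in 20 bins of GC content, and the closest was taken. Genes with a placement whose margin over the next choice was under 0.5 on the log2 scale in any library were left out (29 genes). Of 1731 values with a known point that were put through the same procedure, 1729 (99.9%) were placed right. No group value was there to place 505 values. Left out as well were 2214 entries whose symbol occurs more than once and genes with any value marked as failed or of low data (2769 values). This left 22868 genes with a value in every library.

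A filter of a mean FPKM of at least 0.5 over all libraries left 11581 genes, whose FPKM summed to between 454721 and 499009 per library. FPKM were taken as log2(FPKM + 0.5). Control replicates 1 and 2 have titles that share a number, and the SD of their log2 difference was 0.129, against 0.144 to 0.844 in the other 44 pairs of libraries. They were averaged on the log2 scale and counted as 1 replicate. Where each replicate was left out in turn, these 2 libraries were left out together. The files hold no read counts, so the depth is unknown and no counting intervals are given. Relative depth was read from genes under 0.1 FPKM, as the commonest ratio of the FPKM of control replicate 1 to that of the library. With that replicate at 1, it was 1.04, 2.14 and 1.97 in the other controls, 1.67, 1.84 and 1.95 with DEL22379, and 1.92, 1.82 and 1.72 with SCH772984.

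All 3 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3 (eBayes with trend). Each compound was compared with control, and the compounds with each other. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, intervals are 95% intervals from the moderated fit, and n is the number of replicates in the fit. The 29 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it and fry as an alternative. The 26 lists with at least 3 members tested were adjusted together within each comparison. Counts of list members past the threshold are given adjusted over all genes and adjusted over the list alone. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

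The genes named in the text follow a rule. For each compound against control, it took the 8 largest rises and 8 largest falls among genes past the threshold whose treated replicates all lay on 1 side of all controls and whose mean FPKM was at least 1 in either group. Between the compounds it took 6 each way. It added up to 4 members of each list with the smallest p, MAPK3, and DUSP6, SPRY4, ETV5, FOSL1, EGR1, CCND1, CYP1A1 and CYP1B1. The rule also named an item that is not reported here. Other genes named because a count of calls is spelled out were chosen after their values were seen.

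Correlation of the responses to the compounds was computed across genes. It was set against 100 simulated draws of unchanged groups that share their controls, with each gene drawn independently. It was also set against fits with the controls split between the compounds. The GC trend was found after the data were seen. GC content was taken from GENCODE 29 transcripts for 11264 of the tested genes (97.3%). For each library a loess curve (span 0.5) of the log2 deviation from the mean of all libraries on GC content was subtracted, and the fit was repeated. Slopes with GC content were compared between groups with exact two-sided permutation tests. The other alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 FPKM, median-of-ratios and upper quartile scaling, control replicates 1 and 2 as separate replicates or either alone, each replicate left out, robust eBayes, only the 2 groups compared, an added 2-fold limit and an adjusted p under 0.01. Further alternatives added after the data were seen were a trend on GC content and transcript length, GC removal without SCH772984 replicate 2 or without control replicate 4, both of these libraries left out, placing points by the group value alone and a placement margin of 1.

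The procedure was tested on simulated data of 11260 genes, in which 50 genes each were changed in the SCH772984 group. It called 100% of the changes of -2 (log2), 96% of those of -1, 86% of those of -0.5 and 96% of those of 1, with 16 false calls. With an added GC trend it called 42% of the changes of -0.5 uncorrected and 84% once the trend was removed. The added trend was the curve fitted to each library, and the noise was that left after its removal. This recovery therefore cannot show how the correction acts on other bias or on real changes linked to GC content.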

Results

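Polyadenylated RNA was sequenced from the A375p human melanoma cell line after 2 h with 10 µM DEL22379, 10 µM SCH772984 or the vehicle DMSO. A375 cells carry an activating BRAF mutation, so their ERK pathway is driven from within the cell. SCH772984 blocks the catalytic site of the ERK kinases, and DEL22379 is described in the series as an inhibitor of ERK dimerization. The comparisons therefore ask which transcripts move when ERK is inhibited in each of these ways. The values were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) from 4 DMSO, 3 DEL22379 and 3 SCH772984 libraries. Control replicates 1 and 2 differed less from each other than any other pair of libraries and were counted as 1, so n = 3 in every group. The files give no read counts, and depth relative to control replicate 1 ranged from 1 to 2.14. The labels do not say that the libraries came from separate cultures. Each p therefore measures the spread between samples, which may be technical. After a filter on low values, 11581 genes were tested. Log2 changes are on the log2(FPKM + 0.5) scale, which understates the change of weakly expressed genes. Positions are hg19 coordinates from the authors' deposited table. Their starts were taken to count from 0 and were converted to count from 1. Listed widths matched reference gene widths as end minus start in 3645 genes, and as end minus start plus 1 in 368.

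Several inhibitors of the ERK pathway that ERK itself induces fell with SCH772984. SPRY2 (chr13, 80910112 to 80915086), a Sprouty protein that restrains receptor signalling to RAS, fell from 54.8 ± 0.987 to 12.6 ± 0.698 FPKM (mean ± SD, n = 3 each). Its log2 change was -2.08 (SE 0.0752, limma adjusted p = 1.81e-05), or 4.24-fold lower. DUSP6 (chr12, 89741837 to 89746296), a cytoplasmic phosphatase of ERK, fell 3.68-fold, from 48.2 ± 2.38 to 12.8 ± 1.22 FPKM (limma adjusted p = 4.40e-05, n = 3 each). SPRY4 (chr5, 141689992 to 141704620) fell 2.77-fold, from 72.8 ± 3.24 to 26.0 ± 2.57 FPKM (limma adjusted p = 0.000122, n = 3 each). SPRY1 (chr4, 124317950 to 124324915) fell 2.26-fold, from 5.27 ± 0.315 to 2.06 ± 0.211 FPKM (limma adjusted p = 0.00262, n = 3 each). MYC (chr8, 128748315 to 128753680), a growth regulator with a short-lived mRNA, fell by 1.60 on the log2 scale, from 10.3 ± 1.21 to 3.05 ± 0.318 FPKM (limma adjusted p = 0.000702, n = 3 each).

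In all, 27 genes passed the threshold with SCH772984, 26 lower and 1 higher, and 2926 genes had an unadjusted p under 0.05. Without SCH772984 replicate 2 the unadjusted count was 1120. Among secreted factors, the stress cytokine GDF15 (chr19, 18496968 to 18499986) fell by 1.75 on the log2 scale (adjusted p = 0.00653). The neutrophil attractant IL8 (chr4, 74606223 to 74609433) fell by 1.51 (adjusted p = 0.0133), and HBEGF, a ligand of the EGF receptor, fell by 0.65 (adjusted p = 0.0216). The transcriptional repressor TGIF1 fell by 0.86 (adjusted p = 0.000715). ZFP36L1, which speeds the decay of AU-rich mRNAs, fell by 0.82 (adjusted p = 0.00331), and the Notch effector HES1 fell by 0.67 (adjusted p = 0.0216). The splicing kinase CLK1 (chr2, 201717732 to 201729467) was the only gene that rose, from 14.2 ± 2.02 to 28.5 ± 3.62 FPKM (n = 3 each), a log2 change of 0.98 (SE 0.122, adjusted p = 0.0188). SNURF had the largest fitted fall, by 3.71 (SE 0.327, adjusted p = 0.00267), but it lies within the span listed for SNRPN, whose change of -0.21 did not pass (adjusted p = 0.197). The files hold no reads with which to tell these overlapping genes apart. SLC2A3, a glucose transporter, fell by 0.43. MAPK3, which encodes an ERK kinase, did not pass, with a change of -0.85 (95% interval -1.75 to 0.04, adjusted p = 0.1999). Neither did the ERK-dependent genes ETV5 (-0.00, adjusted p = 0.961), FOSL1 (-0.44, adjusted p = 0.197) and CCND1 (-0.07, adjusted p = 0.344), nor CYP1A1, a target of the aryl hydrocarbon receptor (-0.20, adjusted p = 0.372). Removing the GC trend turned the changes of FOSL1, CCND1 and CYP1A1 to 0.11, 0.0062 and 0.0079, none past the threshold. Without SCH772984 replicate 2 the change of FOSL1 was -0.26, that of CYP1A1 -0.020 and that of MAPK3 -0.38.

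**Figure D1:**
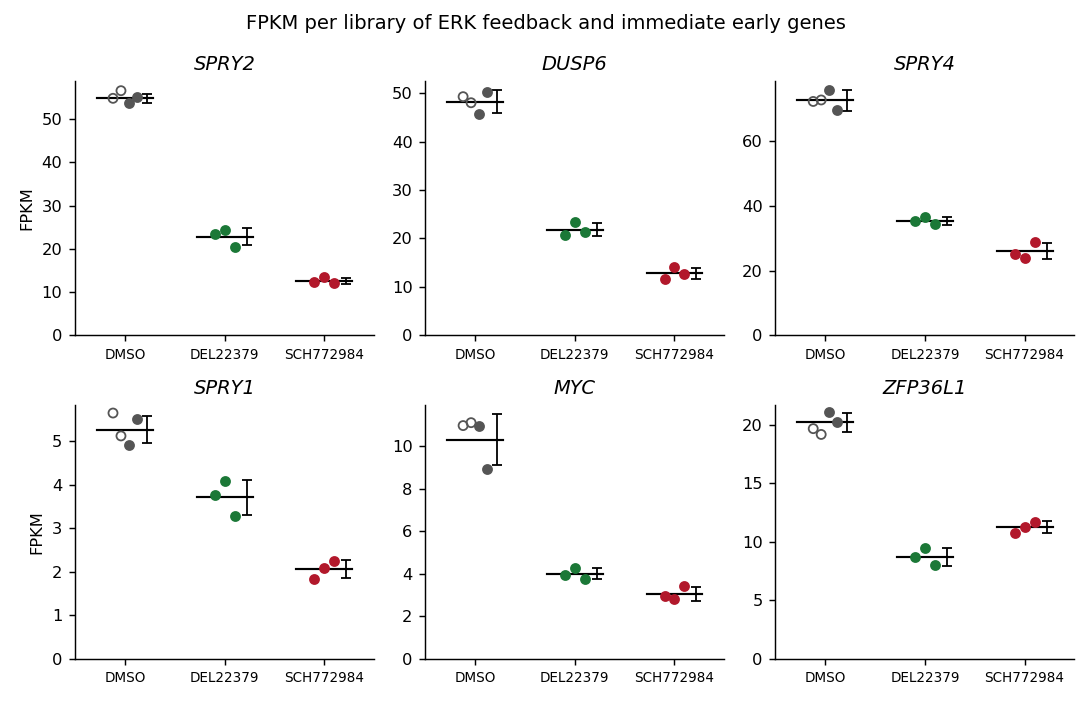
FPKM (vertical axis) of SPRY2, DUSP6, SPRY4, SPRY1, MYC and ZFP36L1 in each library of the 3 groups, with 1 panel per gene. Points are libraries, open circles are control replicates 1 and 2 (counted as 1), lines are means and bars are SD over n = 3; SPRY2 falls from a mean of 54.8 in DMSO to 22.8 with DEL22379 and 12.6 with SCH772984, while ZFP36L1 is lowest with DEL22379 at 8.71.

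The gene lists, the tests and the rule for naming genes were chosen before the data were examined. Of 12 ERK feedback inhibitors tested, 6 fell with SCH772984 when adjusted over all genes (SPRY2, DUSP6, SPRY4, SPRY1, DUSP4 and PHLDA1) and 10 when adjusted over the list alone. Their median log2 change was -0.66 (camera adjusted p = 6.86e-09; adjusted p = 0.0138 with an estimated correlation). Of 9 genes of a published MAPK activity score, 5 fell adjusted over all genes and 7 adjusted over the list alone, with a median of -0.81 (camera adjusted p = 8.64e-09; adjusted p = 0.0138 with an estimated correlation). Those 5 were SPRY2, DUSP6, SPRY4, DUSP4 and PHLDA1, all also in the feedback list, so the 2 lists are not independent. Of 34 immediate early genes, 5 fell adjusted over all genes (MYC, ZFP36L1, EGR1, DUSP1 and TRIB1) and 22 adjusted over the list alone, with a median of -0.37. Their camera adjusted p of 6.24e-10 became an adjusted p = 0.138 with an estimated correlation. Among 10 PEA3 and related transcription factors, MYC and EGR1 were the only members that fell, adjusted over all genes or adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.00339; adjusted p = 0.295 with an estimated correlation). Of 14 NF-kB and cytokine genes, IL8 alone fell adjusted over all genes and 6 fell adjusted over the list alone (median -0.35, camera adjusted p = 0.000193; adjusted p = 0.295 with an estimated correlation). HBEGF alone fell among 11 receptor tyrosine kinases and ligands adjusted over all genes, while 5 fell and 1 rose adjusted over the list alone (median -0.28, camera adjusted p = 0.0429; adjusted p = 0.372 with an estimated correlation). No member of the BCL2 family and death receptor list fell adjusted over all genes, and 5 of 17 fell adjusted over the list alone (median -0.31, camera adjusted p = 0.00784; adjusted p = 0.138 with an estimated correlation). In the same list, PMAIP1, which encodes the death-promoting protein NOXA, changed by -0.62 (adjusted p = 0.0926). None of 10 tubulins passed either way (median -0.61, camera adjusted p = 0.00321; adjusted p = 0.607 with an estimated correlation). Some of these medians rested on SCH772984 replicate 2. Without it they were -0.27 for tubulins, -0.19 for the BCL2 family, -0.18 for receptor tyrosine kinases and -0.20 for NF-kB and cytokine genes, and 1 BCL2 family gene in place of 5 fell adjusted over the list alone.

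The other 18 lists tested were not called for SCH772984. The cascade members themselves (23 genes, median -0.03, camera adjusted p = 0.974), the G1 regulators (20 genes, -0.01, 0.820), the S and G2/M genes (28 genes, 0.13, 0.0782) and the melanocyte lineage genes (15 genes, -0.00, 0.917) had no member past the threshold, adjusted over all genes or adjusted over the list alone. None passed over all genes among aryl hydrocarbon receptor targets (5 genes, median 0.03, camera adjusted p = 0.769), NRF2 genes (15 genes, 0.07, 0.405), ATF4 genes (22 genes, -0.22, 0.385), heat shock genes (13 genes, 0.22, 0.212) and p53 targets (19 genes, -0.23, 0.131). None did among SRF and YAP targets (14 genes, median -0.11, camera adjusted p = 0.223), cholesterol synthesis genes (17 genes, -0.03, 0.704), FOXO targets (14 genes, 0.08, 0.199), glycolysis genes (16 genes, -0.24, 0.111) and housekeeping genes (16 genes, -0.11, 0.478). Adjusted over the list alone, 3 ATF4 genes, 4 p53 targets and 2 glycolysis genes fell, while 3 FOXO targets rose and 1 fell. Ribosome biogenesis genes (18 genes, camera adjusted p = 0.405) had a median of 0.08 and a mean of -0.20, which differ in sign. Median and mean also differed in sign for S and G2/M, NRF2, heat shock and aryl hydrocarbon receptor genes, with means of -0.04, -0.15, -0.06 and -0.02. For the cascade members the median was negative and the test pointed up. Of 17 short-lived mRNAs, CLK1 rose and MYC and PIM3 fell adjusted over all genes, while 2 rose and 6 fell adjusted over the list alone (median -0.08, camera adjusted p = 0.223). Markers of fibroblasts and endothelium (3 genes, median 0.12, camera adjusted p = 0.261) and of epithelium (3 genes, -0.67, 0.518, 1 lower adjusted over the list alone) were not called. The lists of blood cell markers and of replication-dependent histones had 2 genes tested each and the mitochondrially encoded mRNAs 0, so none of these could be tested.

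The SCH772984 calls depended on GC content, the share of G and C bases in a transcript, because libraries differed in how FPKM varied with it. With the GC trend of each library removed, an alternative added after the data were seen, 52 genes passed (1 higher, 51 lower) and 18 of the 27 genes stayed past the threshold. SPRY2 (-2.07), DUSP6 (-1.91), SPRY4 (-1.31), SPRY1 (-1.24), MYC (-1.36), IL8 (-1.67), GDF15 (-1.05) and CLK1 (0.93) were among those 18 genes. The 9 genes lost were CDK5R1, DLX1, DUSP1, DUSP4, EGR1, GPR3, HOXB2, PIM3 and TRIB1. PIM3, a serine/threonine kinase, went from -0.90 to 0.01 when the trend was removed. DUSP1, a nuclear phosphatase of MAP kinases, went from -0.95 (SE 0.0731) to -0.65 (SE 0.120), and the immediate early factor EGR1 from -0.80 (SE 0.0823) to -0.49 (SE 0.164, adjusted p = 0.195). The median of the immediate early genes went from -0.37 to -0.06 with the trend removed. The median of the ERK feedback inhibitors went from -0.66 to -0.61, with 5 of 12 genes lower adjusted over all genes (camera adjusted p = 2.99e-07; adjusted p = 0.195 with an estimated correlation). The median of the MAPK activity score genes went from -0.81 to -0.39, and the estimated correlation gave an adjusted p = 0.148 in that fit. Neither list was thus called in that stricter test once the trend was removed. The alternative test, fry, called both lower there (fry adjusted p = 0.000189 for the feedback inhibitors and 3.25e-05 for the MAPK score genes). It did not call the immediate early genes (fry adjusted p = 0.0701), and it called the melanocyte lineage genes, which camera did not (fry adjusted p = 0.00560). The receptor tyrosine kinase list (median -0.05, camera adjusted p = 0.135) and the NF-kB and cytokine list (median -0.07, camera adjusted p = 0.103) were no longer called. The median went to -0.23 for tubulins, -0.10 for the BCL2 family and -0.14 for the PEA3 factors. All 27 genes stayed past the threshold without SCH772984 replicate 2, the library farthest from all others, and 33 genes passed then. Leaving out control replicates 1 and 2 together left 11 genes and leaving out control replicate 3 left 13. With control replicate 4 and SCH772984 replicate 2 both left out, 2725 genes passed. Those lower had a median GC content of 59.4%, against 47.6% of all tested. The genes SPRY1, SPRY2, SPRY4, DUSP1, DUSP6, MYC, TGIF1, TRIB1, ZFP36L1, CDK5R1 and SNURF passed whichever single replicate was left out.

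Several of the same feedback and immediate early genes fell with DEL22379. ZFP36L1 (chr14, 69254372 to 69262960) fell from 20.3 ± 0.819 to 8.71 ± 0.743 FPKM (n = 3 each), a log2 change of -1.17 (limma adjusted p = 0.001004). SPRY2 fell to 22.8 ± 2.03 FPKM, a log2 change of -1.25 (95% interval -1.43 to -1.08, limma adjusted p = 0.001004, n = 3 each), or 2.38-fold. DUSP6 fell to 21.8 ± 1.32 FPKM, 2.19-fold (limma adjusted p = 0.00166, n = 3 each), and SPRY4 to 35.4 ± 1.13 FPKM, 2.04-fold (limma adjusted p = 0.00166, n = 3 each). MYC fell to 3.99 ± 0.263 FPKM, 2.40-fold (limma adjusted p = 0.00385, n = 3 each).

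In all, 15 genes passed with DEL22379, 14 lower and 1 higher. Of the 11581 genes tested, 510 had an unadjusted p under 0.05, no more than unchanged genes alone would give on average. That count depended on the libraries and the GC trend. It ranged from 192 without DEL22379 replicate 3 to 922 without SCH772984 replicate 2 when each replicate was left out. With the GC trend removed it was 1323 of 11264 genes. PHLDA1 (chr12, 76419227 to 76425556), a gene induced by ERK signalling, fell by 0.89 (adjusted p = 0.0244), HES1 by 0.83 (adjusted p = 0.0123) and the pseudokinase gene TRIB1 by 0.72 (adjusted p = 0.00556). EGR1 fell by 0.68 (adjusted p = 0.0265), CDK5R1, an activator of the kinase CDK5, by 0.62, and TGIF1 by 0.44 (adjusted p = 0.0458). SNURF fell by 2.90 (adjusted p = 0.0201), with the same overlap. The transcription factor SOX9 (chr17, 70117161 to 70122560) fell from 81.8 ± 4.03 to 56.6 ± 3.79 FPKM (n = 3 each), a log2 change of -0.53 (limma adjusted p = 0.0265). The kinase gene SGK1 (chr6, 134490384 to 134639196), induced by serum and glucocorticoids, fell from 91.1 ± 5.28 to 64.4 ± 1.18 FPKM (n = 3 each), a log2 change of -0.50 (limma adjusted p = 0.0186). The noncoding RNA SNHG12 (chr1, 28905050 to 28908366) rose by 0.67 (adjusted p = 0.0458), but did not pass with the GC trend removed (0.77, adjusted p = 0.278). Genes that did not pass were MAPK3 (-0.22, adjusted p = 0.881), ETV5 (-0.05), FOSL1 (-0.18, adjusted p = 0.852), CCND1 (-0.09, adjusted p = 0.852) and CYP1A1 (0.08, adjusted p = 0.890). CYP1B1, named in advance beside CYP1A1, fell under the FPKM filter.

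Among the fixed lists, 4 of 12 ERK feedback inhibitors fell with DEL22379 adjusted over all genes (SPRY2, DUSP6, SPRY4 and PHLDA1) and 6 adjusted over the list alone. Their median was -0.36 (camera adjusted p = 1.01e-15; adjusted p = 0.00249 with an estimated correlation). The same 4 genes fell among the 9 MAPK activity score genes, and 5 fell adjusted over the list alone (median -0.44, camera adjusted p = 1.01e-15; adjusted p = 0.00249 with an estimated correlation). Of 34 immediate early genes, MYC, ZFP36L1, TRIB1, EGR1 and SGK1 fell adjusted over all genes, while 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.03e-14; adjusted p = 0.0739 with an estimated correlation). MYC and EGR1 fell among the 10 PEA3 and related factors, and 3 fell adjusted over the list alone (median -0.20, camera adjusted p = 2.84e-07; adjusted p = 0.0739 with an estimated correlation). The remaining 4 called lists had no member past the threshold over all genes. These were FOXO targets (median -0.16, 3 of 14 lower adjusted over the list alone, camera adjusted p = 2.02e-07; adjusted p = 0.101 with an estimated correlation) and SRF and YAP targets (median -0.20, 2 of 14 lower adjusted over the list alone, camera adjusted p = 0.000383; adjusted p = 0.342 with an estimated correlation). Receptor tyrosine kinases and ligands (median -0.15, 1 of 11 lower adjusted over the list alone, camera adjusted p = 0.00110; adjusted p = 0.133 with an estimated correlation) and p53 targets (median -0.12, 1 of 19 lower adjusted over the list alone, camera adjusted p = 0.0118; adjusted p = 0.101 with an estimated correlation) were the others. The death-related genes BCL2L11 (-0.22) and PMAIP1 (-0.49, adjusted p = 0.374) and the lineage factor MITF (-0.18) did not pass.

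The other 18 lists tested were not called for DEL22379. The camera adjusted p was 0.0508 for short-lived mRNAs, 0.0535 for the BCL2 family, 0.0592 for heat shock genes, 0.0745 for NF-kB and cytokine genes and 0.105 for ribosome biogenesis genes. It was 0.223 for the cascade members, 0.233 for G1 regulators, 0.236 for tubulins, 0.350 for housekeeping genes, 0.372 for glycolysis genes and 0.415 for S and G2/M genes. Aryl hydrocarbon receptor targets, ATF4 genes and cholesterol synthesis genes each gave 0.459, NRF2 genes and melanocyte lineage genes each gave 0.603, and the markers of fibroblasts and of epithelium gave 0.905 and 0.948. MYC was the only member of these lists past the threshold over all genes. Adjusted over the list alone, 3 short-lived mRNAs, 2 BCL2 family genes and 1 cytokine gene fell. Ribosome biogenesis genes had a median of 0.06 and a mean of -0.04, and S and G2/M genes had a median of 0.00 and a mean of -0.02, which differ in sign. The test pointed up against a negative median for NRF2 genes, ATF4 genes and epithelial markers. With the GC trend removed, 33 genes passed (2 higher, 31 lower), 12 of the 15 genes stayed past the threshold, and CDK5R1, EGR1 and SNHG12 were lost. In that fit the ERK feedback inhibitors had a median of -0.28 with 4 of 12 genes lower adjusted over all genes (camera adjusted p = 2.44e-10). Both they and the MAPK activity score genes had an adjusted p = 0.0642 with an estimated correlation. With fry the 2 lists were called lower there (fry adjusted p = 0.000339 and 9.30e-05). The median of the immediate early genes went from -0.23 to -0.12 (camera adjusted p = 2.70e-06, or 0.425 with an estimated correlation). For the PEA3 factors it went from -0.20 to -0.10 (camera adjusted p = 0.000287, or 0.0642 with an estimated correlation). Without SCH772984 replicate 2, which adds to the estimate of spread only, 29 genes passed and all 15 stayed. Leaving out each other replicate in turn left between 5 and 9 genes. SPRY2, DUSP6, SPRY4, MYC and ZFP36L1 passed in every one of those fits. With control replicate 4 and SCH772984 replicate 2 both left out, 1732 genes passed. Those lower had a median GC content of 59.9%, against 47.6% of all tested.

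Some genes that did not pass with all libraries and no correction passed once the GC trend was removed, and the following were chosen after their values were seen. The epithelial-mesenchymal regulator SNAI1 fell with SCH772984 (-1.15, adjusted p = 0.00126) and with DEL22379 (-0.95, adjusted p = 0.00650). The cytokine LIF fell with both compounds too (-1.09 and -0.66, adjusted p = 0.00132 and 0.0340), as did PMAIP1 (-0.76 and -0.49, adjusted p = 9.05e-05 and 0.00198). IL8 reached the threshold with DEL22379 in that fit (-1.04, adjusted p = 0.00305), and TXNIP, an inhibitor of glucose uptake, fell with DEL22379 by 0.50 (adjusted p = 0.00766).

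The direct test between the compounds found 1 gene, and 1214 genes had an unadjusted p under 0.05. SPRY2 was higher with DEL22379 than with SCH772984 by 0.83 on the log2 scale (95% interval 0.66 to 1.002, limma adjusted p = 0.0325, n = 3 each), or 1.78-fold. It passed with the GC trend removed (0.80, adjusted p = 0.00972), but only without DEL22379 replicate 3 and without SCH772984 replicate 2 among the fits that left out 1 replicate, with 0 genes in the 7 others (limma, 400 to 2485 genes with an unadjusted p under 0.05). DUSP6 was higher with DEL22379 by 0.75 (95% interval 0.56 to 0.94, adjusted p = 0.0697), SPRY1 by 0.72 (0.49 to 0.95, adjusted p = 0.132), SPRY4 by 0.44 (adjusted p = 0.283) and MYC by 0.34 (0.10 to 0.59, adjusted p = 0.370), none past the threshold. ZFP36L1 lay the other way, at -0.36 (-0.53 to -0.18, adjusted p = 0.370). The FOXO target TXNIP (-0.57, adjusted p = 0.0809) and the transcription factor gene SOX4 (-0.58, adjusted p = 0.0809) lay lower with DEL22379 without passing. Intervals that spanned 0 included PHLDA1 (-0.32 to 0.16), EGR1 (-0.06 to 0.32) and MAPK3 (-0.26 to 1.53). ETV5 differed by -0.04, CCND1 by -0.02, FOSL1 by 0.27 and CYP1A1 by 0.28, none past the threshold, and FOSL1 turned to -0.11 with the GC trend removed. Missing the threshold does not show that the compounds acted alike on these genes.

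With the GC trend removed, 11 genes differed between the compounds. The 6 genes higher with DEL22379 were SPRY2, DUSP6 (0.76, adjusted p = 0.00972), SPRY1 (0.76, adjusted p = 0.0290), TGIF1 (0.52), RND3 (0.44) and R3HCC1L (0.31). The 5 genes lower with DEL22379 were TXNIP (-0.51, adjusted p = 0.0290), SOX4 (-0.67, adjusted p = 0.0447), CLK1 (-0.79, adjusted p = 0.0447), the kinase gene PLK2 (-0.59, adjusted p = 0.0367) and DDIT4, a brake on mTORC1 (-0.39, adjusted p = 0.0290). Without SCH772984 replicate 2 as well, 7 of these 11 genes stayed past the threshold, and without control replicate 4 only SPRY2 and DUSP6 did. The differences of the 11 genes were nearly the same without that control (SOX4 -0.67, TXNIP -0.51), with adjusted p from 0.0331 to 0.0725. Of the fixed lists, ERK feedback inhibitors were called higher with DEL22379 (median 0.21, 1 of 12 adjusted over all genes, 4 adjusted over the list alone, camera adjusted p = 0.00152; adjusted p = 0.195 with an estimated correlation). With the GC trend removed the median of that list was -0.03 and its mean 0.21, which differ in sign, and 3 members passed over all genes (camera adjusted p = 0.0455; adjusted p = 0.629 with an estimated correlation). MAPK activity score genes (median 0.39, 1 of 9 adjusted over all genes, 3 adjusted over the list alone, camera adjusted p = 0.00722; adjusted p = 0.260 with an estimated correlation), NF-kB and cytokine genes (median 0.31, 3 of 14 adjusted over the list alone, camera adjusted p = 0.000766; adjusted p = 0.398 with an estimated correlation) and tubulins (median 0.45, camera adjusted p = 0.00950; adjusted p = 0.679 with an estimated correlation) were called higher too. Their medians were 0.0074, 0.14 and 0.16 with the GC trend removed, and 0.15, 0.20 and 0.14 without SCH772984 replicate 2, where the tubulins were no longer called (camera adjusted p = 0.133). FOXO targets were called lower with DEL22379, with 0 of 14 adjusted over all genes and 7 adjusted over the list alone (median -0.23, camera adjusted p = 5.81e-06; adjusted p = 0.260 with an estimated correlation), and their median was -0.14 without SCH772984 replicate 2. The other 21 lists tested, among them the immediate early genes (median 0.14, camera adjusted p = 0.0761) and the PEA3 factors (median 0.16, camera adjusted p = 0.806), were not called.

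**Figure D2:**
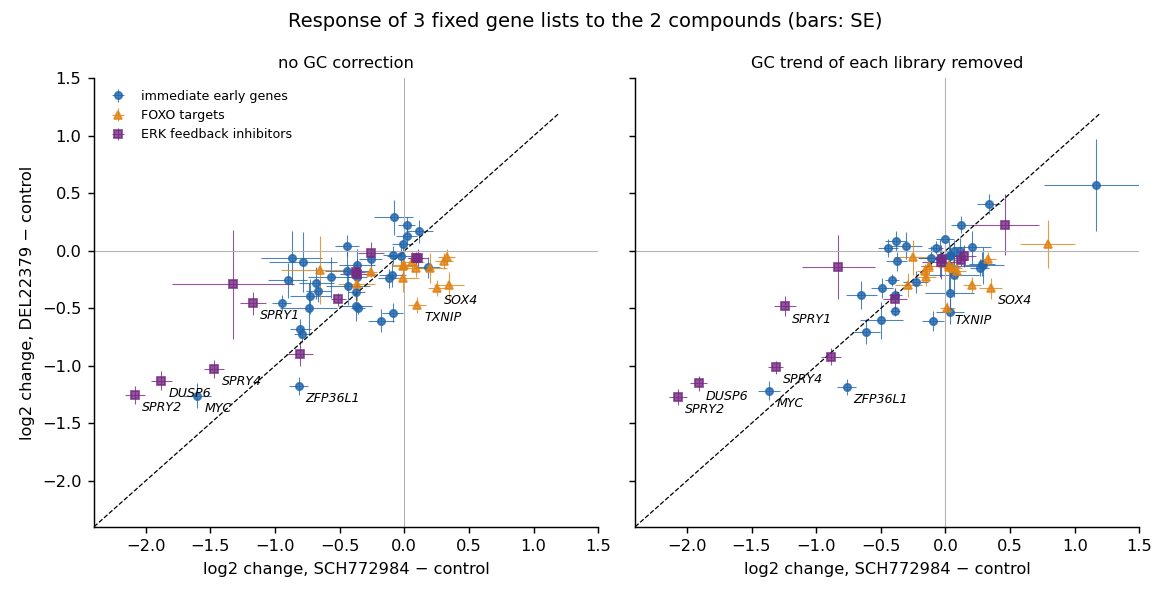
Log2 change with SCH772984 (horizontal) against that with DEL22379 (vertical), both minus control, for ERK feedback inhibitors (squares), immediate early genes (circles) and FOXO targets (triangles), without GC correction on the left and with the GC trend removed on the right. Bars are SE (n = 3 per group) and the dashed line marks equal change; SPRY2 lies at -2.08 and -1.25 on the left and at -2.07 and -1.27 on the right, above the line in both.

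Of 26 genes lower with SCH772984 and 14 lower with DEL22379, 12 were lower with both, against the same controls. They were SPRY2, SPRY4, DUSP6, PHLDA1, MYC, EGR1, ZFP36L1, TRIB1, HES1, TGIF1, CDK5R1 and SNURF. SOX9 and SGK1 were called with DEL22379 alone, yet the compounds did not differ past the threshold at SOX9 (-0.40, adjusted p = 0.227) or at SGK1 (-0.14, adjusted p = 0.370). With the GC trend removed, 24 genes were lower with both among 51 and 31, and SGK1 was among them. Across all 11581 genes the changes correlated with Pearson's r = 0.743 and a Spearman coefficient of 0.649, but genes are not independent replicates and both changes share the controls. Simulated unchanged groups with shared controls gave a mean r of 0.496 (SD 0.0203 over 100 draws). Each gene was drawn independently there. The draws therefore leave out variation shared across genes, such as the GC trend, and cannot set the range of r in unchanged groups. With the controls split between the compounds, r was 0.525 or 0.805, depending on which controls went to which compound.

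The libraries differed in how expression varied with GC content. Each slope is the log2 deviation from the mean of all libraries per 10 percentage points of GC content, over 11264 genes. The slopes were 0.169, 0.174, 0.300 and -0.0963 in control replicates 1 to 4, and 0.0710, 0.0443 and -0.00891 in the DEL22379 libraries. They were -0.0489, -0.522 and -0.0812 in the SCH772984 libraries. The mean slope was 0.125 ± 0.202 for controls, 0.0355 ± 0.0407 for DEL22379 and -0.218 ± 0.265 for SCH772984 (SD, n = 3 each). Neither compound's slopes differed from the controls' in an exact two-sided permutation test (p = 0.3 for SCH772984 and 0.5 for DEL22379), and 3 against 3 cannot give a p under 0.1. Across genes, the log2 change with SCH772984 had a Spearman correlation of -0.79 with GC content, and the change with DEL22379 one of -0.39. Removing the trend moved the change of MAPK3 with SCH772984 from -0.85 to -0.23.

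**Figure D3:**
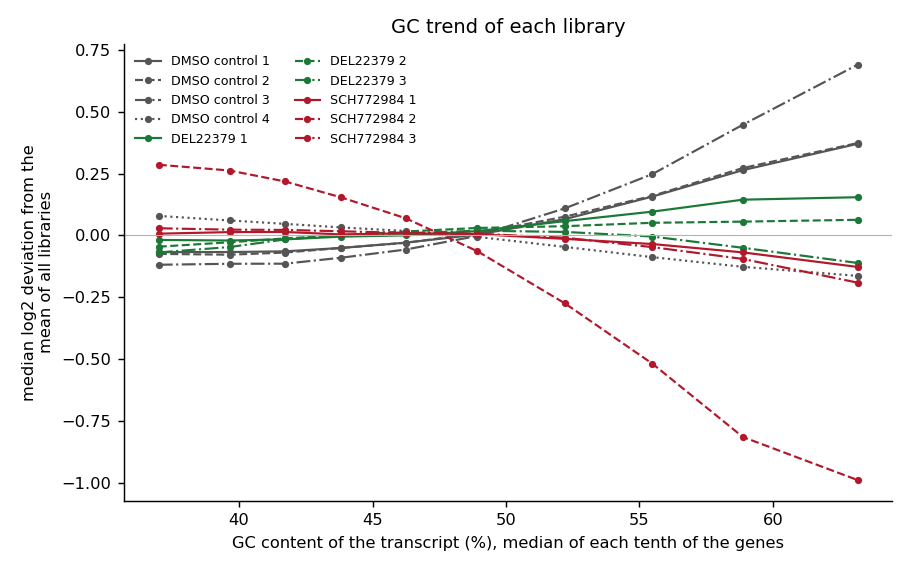
Median log2 deviation from the mean of all libraries (vertical) against the median GC content in percent of each of the bins that hold equal numbers of genes (horizontal), with 1 line for each of the 10 libraries, coloured by group. SCH772984 replicate 2 falls most steeply, at a slope of -0.522 per 10 points, and control replicate 3 rises most, at 0.300.

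The authors' deposited tables compared each compound with control by their own pipeline. For SCH772984, the authors' deposited table listed 12577 genes, of which 2060 had a q-value under 0.05, 65 higher and 1995 lower. These included 26 of the 27 genes called here; SNURF was the exception, with an authors' q-value of 0.452. For DEL22379, the authors' deposited table listed 12613 genes, of which 585 had a q-value under 0.05, 12 higher and 573 lower. These included 13 of the 15 genes called here; SNURF (q-value 0.622) and SNHG12 (q-value 0.152) were the exceptions. The genes called lower in the authors' deposited tables had a median GC content of 60.4% for SCH772984 and 61.7% for DEL22379, against 47.9% for all genes listed. Of 1804 such genes for SCH772984 that could be tested with the GC trend removed, 35 passed and 1442 lay below 0, and the median log2 change of all 1804 went from -0.75 to -0.23. Of 530 for DEL22379, 28 passed and 529 lay below 0, and the median of all 530 went from -0.44 to -0.24. Both sets were chosen as lower in these same libraries. Their lying mostly below 0 is therefore partly fixed by that choice and does not show that the falls are real.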

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

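All tests of explanations in this part were chosen after the results were seen. SPRY2 was singled out because the responses to the compounds differed in a direct test: its level with DEL22379 was higher than that with SCH772984 by 0.83 on the log2 scale, since it fell less with DEL22379 (limma adjusted p = 0.0325).

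GC-rich genes were lower in SCH772984 libraries than in controls, with mean slopes of -0.218 and 0.125 per 10 points of GC content. The control slopes alone spanned 0.397, more than the difference of -0.343 between the group means, so GC bias that differs between libraries is a candidate explanation; without control replicate 4 that span is 0.129. The SCH772984 slopes spanned 0.474, but this rests on replicate 2, without which the span is 0.0323 and the difference from control -0.190. An effect of SCH772984, as the whole cause or as part of it, therefore cannot be told apart from bias between libraries, since the exact two-sided permutation p was 0.3 and the smallest possible is 0.1.

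Of 54 genes tested in the ERK feedback, PEA3, MAPK score and immediate early lists, 11 fell with SCH772984 and 9 with DEL22379; the immediate early list as a whole was not called with an estimated correlation (adjusted p = 0.138 and 0.0739), and with the GC trend removed its median with SCH772984 was -0.06. Against the GC trend as their cause, 7 of these 11 stayed past the threshold in the same direction with the trend removed, and against SCH772984 replicate 2 alone, 11 of 11 stayed without it. The call ended for DUSP1 (-0.95, SE 0.0731, to -0.65, SE 0.120), DUSP4 (-0.51, SE 0.0583, to -0.39, SE 0.0930), EGR1 (-0.80, SE 0.0823, to -0.49, SE 0.164) and TRIB1 (-0.79, SE 0.0658, to -0.62, SE 0.110), because the change shrank and its error grew; the 95% intervals of all 4 stayed below 0, which argues against the GC trend as the whole cause there and leaves it open as part of it. General loss of short-lived mRNAs as the cause of the fall in feedback genes is argued against for SCH772984 by the 17 listed short-lived mRNAs. Their median change was 0.018 (SD 0.489 between members) with the GC trend removed, against -0.61 for the 12 feedback genes (permutation p = 0.00421, two-sided). This permutation p and the one below for DEL22379 treat genes as independent, while camera estimated a correlation of 0.199 among the feedback genes in that fit. For the immediate early genes with SCH772984, the comparison cannot decide on general loss. Their median of -0.06 in that fit and the short-lived median of 0.018 both lay near 0, and 7 of the 17 short-lived mRNAs lay below 0. MYC, MCL1, IER2, JUNB, KLF10 and GADD45B are in both lists. For DEL22379 the short-lived median of -0.0050 lay near 0, against -0.28 for the feedback genes (permutation p = 0.0132, two-sided). The gap is less than the SD between members, 0.349, so general loss is left open there. That SD measures the spread of members and not the error of a median. An effect of ERK inhibition on the feedback and immediate early genes remains as a hypothesis, found and tested on the same data.

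With the GC trend removed, 11 genes differed between the compounds. Of these, 3 (DDIT4, R3HCC1L and TXNIP) passed against control with DEL22379 and lay farther from control than with SCH772984. PLK2 lay farther too (-0.43 with DEL22379, 0.16 with SCH772984), but did not pass against control with DEL22379 (limma adjusted p = 0.0783). The other 7 lay nearer to control with DEL22379. Among these 7, SOX4 lay on opposite sides of control (-0.32 with DEL22379, 0.35 with SCH772984) and passed against control with neither compound. The limit of 3 was set once the count was known. The test therefore cannot decide whether DEL22379 gave a uniformly weaker form of the SCH772984 response. Against the GC correction itself as the source of the differences, only 2 of the 11 uncorrected differences (DDIT4 and RND3) lay outside the corrected 95% interval. For these genes the correction decides the size of the difference. The calls rest on the correction for 10 of the 11 genes, since SPRY2 alone also passed without it. Against SCH772984 replicate 2 alone, 7 of the 11 stayed past the threshold without it, while CLK1 (-0.79), DDIT4 (-0.40), PLK2 (-0.53) and R3HCC1L (0.31) kept nearly the same difference at adjusted p from 0.0536 to 0.0844; without control replicate 4, which bears mainly on the estimate of spread, SPRY2 and DUSP6 alone stayed, with differences nearly the same. A response to DEL22379 that is more than a weaker form of that to SCH772984 thus rests on few genes and stays a hypothesis.

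Each comparison has 10 splits of its 6 samples, which cannot give a share under 0.05. In each, 1 split, the real one, gave as many genes as observed. The real split gave 27 genes for SCH772984 against control, 15 for DEL22379 against control and 1 between the compounds, and the highest of the other splits gave 0 in all 3 (limma).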

How the results depend on the processing

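The alternatives on GC content, on placing decimal points and on leaving out 2 libraries together were added after the data were seen. No paired analysis was possible because sample titles run through the groups and share no replicate numbers. Alternatives based on read counts (another normalization, another model, no count filter) were not run, since the files hold no counts. Across alternatives, 8856 values for named genes kept direction and side of the threshold, 240 no longer passed, 194 newly passed and 3 reversed. The 8856 include genes that passed in neither fit. Among the 43 calls of the 3 comparisons, 25 were lost without control replicates 1 and 2 together. Without control replicate 3, 24 were lost, and with only the 2 groups compared 22. All 43 stayed without SCH772984 replicate 2, and 31 stayed with the GC trend removed. For the lists, 275 stayed, 25 no longer passed and 12 newly passed. Pseudocounts, scaling, robust eBayes, either of control replicates 1 and 2 alone and the ways of placing decimal points kept all 3 counts within 1.5 times.

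For SCH772984 against control the 27 genes became 59 with control replicates 1 and 2 separate, 12 with only the 2 groups compared (fewer samples), 52 with the GC trend removed, 53 with GC and length trends removed, 60 with GC removed and without SCH772984 replicate 2, and 58 with GC removed and without control replicate 4. A 2-fold limit left 8 and an adjusted p under 0.01 left 16, by construction. Leaving out each replicate gave 11 to 33. The counts furthest from 27 were 11 without control replicates 1 and 2 together, 13 without control replicate 3 and 17 without DEL22379 replicate 2.

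For DEL22379 against control the 15 genes became 31 with control replicates 1 and 2 separate, 33 with GC removed, 28 with GC and length removed and 42 with GC removed and without SCH772984 replicate 2. They became 6 with a 2-fold limit and 6 at an adjusted p under 0.01. Leaving out each replicate gave 5 to 29, with 29 without SCH772984 replicate 2 and 5 to 9 without each of the others. Without both control replicate 4 and SCH772984 replicate 2, 2725 genes passed for SCH772984 and 1732 for DEL22379. The genes lower there had a median GC content of 59.4% and 59.9%, against 47.6% of all tested; that fit was not repeated with the GC trend removed.

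Between the compounds the 1 gene became 2 with no filter, 2 at 5 FPKM, 5 with control replicates 1 and 2 separate, 11 with GC removed, 14 with GC and length removed, 8 with GC removed and without SCH772984 replicate 2, 2 with GC removed and without control replicate 4, and 3 without both libraries. It became 0 with only the 2 groups compared (limma, 910 with an unadjusted p under 0.05), 0 with a 2-fold limit and 0 at an adjusted p under 0.01 (1214 unadjusted in both). Leaving out each replicate gave 0 to 2, with 2 only without SCH772984 replicate 2 and 1 without DEL22379 replicate 3. It gave 0 without control replicates 1 and 2 together, without control replicate 3 and without control replicate 4 (799, 1058 and 1516 unadjusted). It also gave 0 without DEL22379 replicate 1 or 2 (1135 and 400 unadjusted) and without SCH772984 replicate 1 or 3 (2485 and 1436 unadjusted).

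The correlation of 0.743 (0.496 in simulated unchanged groups) became 0.690 with GC removed (0.510 in simulated unchanged groups), 0.720 at 5 FPKM, 0.525 and 0.805 with the controls split, and 0.429 and 0.680 with the controls split and GC removed. The change of PIM3 with SCH772984, -0.90, reversed to 0.014 with GC removed, 0.035 with GC and length removed and 0.27 with GC removed and without control replicate 4; its GC content is 67.1%, and the correction acts on GC content. For the other counts above the cause was not tested, also where fewer samples were fitted, apart from the stricter thresholds named. Depth is unknown, so changes of genes near the filter cannot be bounded by counting.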

Other observations

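The tests reported in this part were all chosen after the results were seen, and the genes named were chosen after their values were seen. Some further genes passed with SCH772984 once the GC trend was removed, without forming a tested group. RND3 fell by 0.77 (adjusted p = 0.000192), the angiogenic factor VEGFA by 0.66 (adjusted p = 0.0244), and TNFAIP3, an inhibitor of NF-kB signalling, by 0.60 (adjusted p = 0.0251). The fixed list of NF-kB and cytokine genes, which includes TNFAIP3, was not called for SCH772984 in that fit (camera adjusted p = 0.103; adjusted p = 0.341 with an estimated correlation), with 0 members higher and 4 lower adjusted over all genes, and 4 higher and 5 lower adjusted over the list alone. With DEL22379, CYR61, a secreted matrix protein and target of SRF and YAP, fell by 0.61 (adjusted p = 0.0258). The growth factor GDNF fell by 0.63 (adjusted p = 0.0107) and DDIT4 by 0.42 (adjusted p = 0.00766) in the same comparison, while CDKN2AIP rose by 0.41 (adjusted p = 0.0151) and R3HCC1L by 0.38 (adjusted p = 0.00360).

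The principal component with the largest variance took 81.6% of the variance over the libraries, and its loadings had a Spearman correlation of size 0.844 with GC content across genes. All pairs of libraries with SCH772984 replicate 2 had an SD of the log2 difference of at least 0.473, and all other pairs of at most 0.429.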
